A study of Mus musculus with 9 samples.

How the data were processed

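The series holds 9 Affymetrix arrays of mouse thyroid RNA. Each array was hybridised with RNA of 1 pool of thyroids, and there was 1 pool for each of 3 genotypes (wild type, E7 transgenic, RET-PTC transgenic) at each of 3 ages (2, 6 and 10 months). The number of mice in a pool, their sex, the harvest time and the scan date were not given in the sources used here. Labelling and extraction are described in the labels' protocols as the manufacturer's standard procedure with a biotin label.

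The deposited values are on a log2 scale, as their range shows, with 45101 probe sets per array. Per the submitters' processing notes the authors used GCRMA, a background correction by probe sequence followed by quantile normalization and a summary per probe set. Its version was not given in the sources used here. The scanner files were not used here, so the background correction and the first normalization could not be varied. Normalization of this kind sets the arrays to nearly one distribution, so a shift of most genes in one genotype would not be visible in these values. The median over all probe sets was between 3.85 and 3.95 on every array. GCRMA compresses dim probe sets towards a low plateau, and values under 4 were treated as bounds rather than levels.

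Probe sets were named with the platform's annotation table, updated through Entrez identifiers with RefSeq genes of assembly GRCm38.p6, which changed 0 symbols. Of the 45101 probe sets, 34945 had 1 gene symbol, 932 had several, 9160 were unnamed here and 64 were manufacturer's controls. Each of 18193 genes was represented by the probe set with the highest mean over the 9 arrays, chosen without regard to group. Genes with a log2 value of at least 4 on at least 3 of the 9 arrays were tested, which kept 11370 genes. A gene under 4 on all arrays of a group is given as "at least N-fold", the brighter group's mean against a value of 4. In comparisons of genotypes and of ages, a named gene under 4 on only some arrays of a group keeps its log2 difference. The report adds the difference with those values set to 4. Slope differences of such genes are given without that addition. List genes with no singly named probe set were not analysed here.

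Genotypes were compared with limma (version 3.58.1, R version 4.3.3) by lmFit and eBayes, with genotype and age as factors over all 9 arrays. This left 4 residual degrees of freedom. Each genotype comparison is thus an average over the 3 ages, and its error is how much the difference varied between ages plus array noise. The 10-month and 2-month arrays were compared in the same fit. Age slopes came from a fit with genotype, age in months and their interaction, which left 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and the threshold was 0.05. Nothing in the labels says that pools of one genotype are replicates beyond their age. The p-values rest on the variation that genotype and age leave over in these pools. None of them measures the spread between pools of the same genotype and age. Standard deviations over the 3 pools of a genotype include the effect of age. The small number of arrays limits the precision of every value, and a difference at a single age compares 1 pool with 1 pool and has no test.

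Before the data were examined, 35 gene lists were fixed for thyroid function, growth pathways and the other cell types a thyroid dissection could hold. The 31 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside each call stands the adjusted p with a correlation estimated from the data. Lists can share members, and the 2 transgenic comparisons share the wild-type arrays. At single ages, the median of a list was placed among 10000 random lists of the same size matched on mean expression. The random genes were drawn independently, so a list of genes that vary together reaches an extreme percentile easily. These percentiles do not measure the spread between pools.

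The genes named were also chosen by a rule fixed before the data were examined. For each transgenic genotype against wild type these were the 10 largest rises and 10 largest falls among genes past the threshold with the same sign at all 3 ages. For the other comparisons they were the 5 largest in each direction, or the 5 with the smallest p where fewer passed. Up to 4 members of each list with the smallest p could be named as well. Genes named outside this rule are marked as such.

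The gene test was tested on simulated data with the real gene means, the eBayes variances of the genotype fit and 200 changed genes among 11370. For a change of 1 on the log2 scale it recovered 80.0% for E7 against wild type, 81.5% for RET-PTC against wild type, 81.0% for RET-PTC against E7 and 83.0% for 10 against 2 months. Unchanged genes called falsely numbered 11, 6, 5 and 9 in the same order, and 13, 16, 9 and 15 for a change of 2. For slopes, a change of 2 over the age range was recovered in 56.5% of the RET-PTC genes and 52.5% of the E7 genes, and a change of 1 in 0%. False calls for the slope change of 2 numbered 9 and 8. The simulated noise was normal and independent between genes and arrays. These rates therefore do not cover genes that vary together or differences between pools of the same genotype and age.

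Alternatives tried were no filter and a filter at 6, centring of arrays, a further quantile normalization, trend and robust variance estimates, other rules for probe sets, other age terms, each age or genotype left out, and each array left out. Among 203 combinations of a gene and a comparison with further probe sets, 16 had a probe set of the opposite sign, and in 3 of them that probe set passed the threshold. Those were Sdha in both comparisons with E7 and Ywhaz in RET-PTC against wild type. Figures were drawn with matplotlib (version 3.10.9).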

Results

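Thyroid gene expression was measured in wild-type mice and in 2 transgenic strains, E7 and RET-PTC, to follow the steps of thyroid tumour development with age. E7 is an oncoprotein of human papillomaviruses that binds the retinoblastoma protein and releases E2F transcription factors. RET-PTC proteins are fusions of the RET tyrosine kinase that arise in human papillary thyroid cancer, and the labels do not say which fusion was used. There were 3 arrays per genotype, from pools taken at 2, 6 and 10 months, and so no replicate of any genotype at any age. Over the 11370 genes tested, arrays of one genotype correlated at 0.964 to 0.993, wild-type with RET-PTC arrays at 0.945 to 0.961 and E7 with the other arrays at 0.894 to 0.932. The first principal component held 54.4% of the variance and separated the E7 arrays, at 51.1 to 67.2, from all others, at -32.1 to -26.0. The second held 21.2% and separated wild-type arrays, at 24.6 to 36.3, from RET-PTC arrays, at -30.9 to -29.8.

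The mouse probe sets for the genes joined in RET fusions were read first. Ret was at 9.05 ± 0.36 in wild type, 9.32 ± 0.40 in E7 and 8.25 ± 0.23 in RET-PTC pools (log2, SD, n = 3). Ncoa4 was at 11.55 ± 0.28, 11.20 ± 0.03 and 10.84 ± 0.10 in the same order, and Ccdc6 at 9.00 ± 0.24, 9.32 ± 0.08 and 9.17 ± 0.06. It is not known here whether these probes lie in the transgene, and the viral E7 sequence has no probe set named here, so these values check nothing about the labels.

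E7 against wild type asks what the viral oncoprotein changes in the thyroid. Genes of DNA replication and cell division were higher in E7 pools at all 3 ages, while markers of fat and of the calcitonin-producing C cells were lower (adjusted p = 0.705, 0.863, 0.705 and 0.404 with an estimated correlation). Of 11370 genes tested, 4630 passed, 2279 higher and 2351 lower, with 633 higher and 765 lower by at least 2-fold. Lockd, a long non-coding RNA next to Cdkn1b, rose at least 17.9-fold (8.16 ± 0.61 against 2.83 ± 0.18 on the log2 scale, SD, n = 3, limma adjusted p = 0.000104). Krtap17-1, a keratin-associated protein gene, rose at least 11.5-fold and E2f7, an atypical E2F repressor, at least 8.0-fold. Fignl1, which acts in homologous recombination, rose by 4.46 ± 0.43 (SE) on the log2 scale. Ckap2, a spindle protein gene, rose by 4.40, Cep55, which acts in cytokinesis, by 4.23, the cohesin acetyltransferase gene Esco2 by 4.17 and the checkpoint kinase gene Chek1 by 4.04. Wfikkn2, which encodes a secreted inhibitor of growth differentiation factors, rose by 4.15 ± 0.13 (SE) and Fam47e by 4.21 ± 0.34 (SE). Among the falls, Ucp1, the uncoupling protein of brown fat, was at least 179-fold lower (3.10 ± 0.48 against 11.48 ± 0.43, limma adjusted p = 8.50e-05). Retn, which encodes the adipokine resistin, was at least 92.1-fold lower, Pck1, an enzyme of gluconeogenesis and glyceroneogenesis, at least 61.0-fold, Tmem45b at least 49.5-fold, the lipid droplet gene Cidec at least 34.2-fold and the paraoxonase gene Pon1 at least 27.5-fold. Cidea, another lipid droplet gene, fell by 6.92 on the log2 scale, the neuroendocrine gene Resp18 by 6.92, Cyp2e1 by 6.37 and the secretogranin gene Scg2 by 6.31. Of the 3 arrays of the lower group, values were under 4 on 2 for Fignl1, Ckap2 and Resp18 and on 1 for Cep55, Esco2, Fam47e, Cidea and Cyp2e1. With these set to 4, the differences were 4.32, 4.32 and -6.06, and 4.04, 4.08, 4.09, -6.88 and -6.09.

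The cell cycle lists moved together in E7. Of 38 tested genes of DNA replication and E2F targets, 35 rose and 0 fell, with a median change of 2.21 on the log2 scale (4.62-fold; camera adjusted p = 4.52e-18, adjusted p = 0.705 with an estimated correlation). Mcm3, Mcm2 and Mcm6, parts of the replicative helicase, rose by 3.09 ± 0.15, 2.50 ± 0.13 and 2.31 ± 0.12 (SE), and Rbl1, the retinoblastoma relative p107, by 1.98 ± 0.08. All 31 mitosis genes rose, with a median of 3.10 (8.60-fold; camera adjusted p = 2.74e-13, adjusted p = 0.863 with an estimated correlation). With values under 4 set to 4, the mitosis median was 2.89, since 9 of its genes were under 4 on all arrays of a group. Pbk, a mitotic kinase gene, rose by 3.60, Nusap1, a spindle protein gene, by 3.53, Cdk1, the main mitotic kinase gene, by 3.10 and Cdc20, an activator of the anaphase-promoting complex, by 2.85. The mitosis median was 4.52 at 2 months, 2.83 at 6 months and 2.02 at 10 months, each at the 100th percentile of the random lists. Among 17 p53 target genes 4 rose and 3 fell, with Cdkn1a, a cyclin-dependent kinase inhibitor, up by 1.17 ± 0.15 (SE) and the proapoptotic gene Pmaip1 up by 1.79 ± 0.32, and the list was not called (camera adjusted p = 0.399). The 4 that rose include Eda2r, which was under 4 on 2 of 3 E7 and 3 of 3 wild-type arrays, with a difference of 0.01 when these are set to 4. The counts of these 3 lists were the same when adjusted over the list alone.

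Thyroid genes moved in both directions in E7. Of 19 tested genes of thyroid hormone synthesis and differentiation, 6 rose and 6 fell (median -0.19, camera adjusted p = 0.926). Pax8, a transcription factor of follicular cells, rose by 1.30 ± 0.11 (SE), from 9.58 ± 0.16 to 10.88 ± 0.06, and Fcgbp, a mucus-type secreted protein gene, by 1.55 ± 0.23. Gpx3 and Sod3, secreted antioxidant enzymes, fell by 3.62 ± 0.20 and 3.30 ± 0.51. Of 16 genes of MAPK pathway output, 7 fell and 0 rose (median -0.27, camera adjusted p = 0.144), among them the transcription factor gene Etv5 by 2.82 ± 0.32 (SE), the phosphatase gene Dusp6 by 1.19 ± 0.15 and Spred1, a pathway inhibitor gene, by 0.82 ± 0.11. Dusp4 was at least 1.24-fold lower. Of 26 genes known to be raised in human papillary thyroid cancer, 4 rose and 5 fell. Hmga2, a chromatin protein gene, was at least 16.2-fold lower, while the mucin gene Muc1 rose by 2.79 ± 0.29 and the receptor gene Met by 0.75 ± 0.13. Of 19 genes known to be lowered in that cancer, 8 rose and 7 fell, among them the metallothionein gene Mt1 by 1.41 ± 0.10. For the last 2 lists the median and the mean differed in sign (medians 0.20 and 0.13, means -0.10 and -0.30), and neither was called (camera adjusted p = 0.820 and 0.919). Of 18 epithelial genes 6 rose and 0 fell (median 0.31, camera adjusted p = 0.00723, adjusted p = 0.863 with an estimated correlation), with Grhl2, an epithelial transcription factor gene, up by 1.20 ± 0.09 (SE), the claudin gene Cldn3 by 0.90 ± 0.10 and the adhesion gene Epcam by 0.71 ± 0.09. The other Epcam probe set changed by -0.27, short of the threshold. Of 19 immediate early genes 5 rose and 3 fell (camera adjusted p = 0.399), with Atf3 up by 2.21 ± 0.38 and Fos by 1.48 ± 0.30. Muc1 was under 4 on 2 of 3 wild-type arrays, and Etv5 and Sod3 on 1 of 3 E7 arrays, and with these set to 4 the differences were 2.46, -2.67 and -3.26. In the MAPK list 1 gene rose and 7 fell when adjusted over the list alone, and the counts of the other 5 lists were the same.

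Markers of fat fell in E7 with genes of lipid synthesis and respiration. Of 13 adipocyte genes 12 fell and 0 rose, with a median of -4.17 (18.0-fold lower; camera adjusted p = 2.32e-09, adjusted p = 0.705 with an estimated correlation). Fabp4, the fatty acid binding protein of adipocytes, fell by 1.73 ± 0.15 (SE), from 14.60 ± 0.15 to 12.87 ± 0.13. Of 18 genes of fatty acid and cholesterol synthesis 11 fell and 0 rose (median -0.49, camera adjusted p = 0.000666, adjusted p = 0.705 with an estimated correlation). Scd1, the stearoyl-CoA desaturase gene, fell by 4.72 ± 0.23 (SE), the acetyl-CoA synthetase gene Acss2 by 3.75 ± 0.22 and Fasn, the fatty acid synthase gene, by 3.34 ± 0.18. Fat tissue expresses these genes strongly, and the adipocyte markers moved with them. Of 25 genes of oxidative phosphorylation 24 fell and 0 rose (median -0.68, camera adjusted p = 2.25e-09, adjusted p = 0.841 with an estimated correlation), while the adipocyte median stood at -4.17 and that of muscle at -1.51. Ndufs3, of complex I, fell by 0.91 ± 0.11 (SE) and Cox5a, of complex IV, by 0.71 ± 0.09. Of 17 genes of hypoxia and glycolysis 2 rose and 7 fell (camera adjusted p = 0.257), with the hexokinase gene Hk2 down by 2.85 ± 0.36 and Vegfa up by 0.93 ± 0.11. Pgk1, also one of 8 reference genes of which 2 fell and 0 rose, fell by 0.86 ± 0.11, and the reference list had a median of 0.03 and a mean of -0.10 (camera adjusted p = 0.919). Adjusted over the list alone, 13 adipocyte and 25 oxidative phosphorylation genes fell, and the counts of the other lists here were the same.

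Neuroendocrine markers of C cells fell in E7 in 10 of 11 tested genes, with 0 rising and a median of -4.03 (16.4-fold lower; camera adjusted p = 4.51e-07, adjusted p = 0.404 with an estimated correlation). With values under 4 set to 4, the C-cell median was -3.29 and that of muscle, given next, -1.28. Chgb, a chromogranin gene, fell by 5.44 ± 0.23 (SE), Scg5 by 2.75 ± 0.16 and Snap25, of the exocytosis machinery, was at least 9.75-fold lower. At single ages the C-cell median was -4.37, -4.55 and -3.88 at 2, 6 and 10 months. Of 20 skeletal muscle genes 5 fell and 0 rose (median -1.51, camera adjusted p = 0.00112, adjusted p = 0.877 with an estimated correlation), with the myoglobin gene Mb down by 1.73 ± 0.39 (SE) and the nebulin gene Neb by 1.34 ± 0.32. The muscle median was -3.21 at 2 months and -0.59 and -0.56 at 6 and 10 months, and over all ages it was -0.68 without the 2-month E7 and -0.90 without the 2-month wild-type pool. Of 6 parathyroid genes 1 rose and 3 fell (camera adjusted p = 0.270), with the calcium receptor gene Casr down by 3.15 ± 0.40, Gata3 at least 4.54-fold lower and the parathyroid hormone gene Pth down by 1.78 ± 0.52. Of 6 airway genes 2 fell and 0 rose (camera adjusted p = 0.117), Cyp2f2 at least 11.5-fold and Bpifa1 at least 8.6-fold. Both tested thymocyte genes fell, Cd1d1 by 3.20 ± 0.25 (SE) and Satb1 at least 7.76-fold. Of 6 cartilage genes 2 rose and 3 fell (camera adjusted p = 0.919), with Cnmd down by 3.14 ± 0.47 and Sox9 up by 0.89 ± 0.11, and of 5 squamous genes 1, the plakophilin gene Pkp1, rose by 2.00 ± 0.21 (camera adjusted p = 0.820). The squamous list had a median of -0.03 and a mean of 0.28. Chgb and Casr were under 4 on 2 of 3 E7 arrays and Cnmd and Neb on 1, and with these set to 4 the differences were -4.91, -2.70, -3.00 and -0.97. When adjusted over the list alone, the counts of these lists were the same.

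Immune and stromal lists were mostly below the threshold in E7. Of 19 macrophage genes 0 passed in either direction (median 0.12, camera adjusted p = 0.919), and 0 of 3 neutrophil genes passed. At 2, 6 and 10 months the macrophage median was -0.334, 0.827 and -0.406, in single pools without a test. In the same order, chemokines were at -0.435, 0.833 and -0.197 and interferon genes at -0.389, 0.407 and -0.254. Fibroblasts were at -0.604, 0.166 and -0.658. The T and NK cell medians were below and the endothelial medians above wild type at each age. Of 26 genes of fibroblasts and extracellular matrix 1 rose and 6 fell (median -0.31, camera adjusted p = 0.0867), with the growth factor receptor gene Pdgfra down by 2.39 ± 0.28 (SE) and the smooth muscle actin gene Acta2 by 1.80 ± 0.13. Of 18 endothelial genes 4 rose, such as the receptor gene Kdr by 0.71 ± 0.09, and 4 fell, such as Vwf by 1.60 ± 0.29 (median 0.22, mean -0.04, camera adjusted p = 0.555). Of 15 chemokines and cytokines 1 rose, Ccl2 by 1.30 ± 0.28, and 2 fell, among them Cxcl13, which attracts B cells, by 4.20 ± 0.68 (camera adjusted p = 0.919). Of 26 interferon response genes 4 fell, such as Ifit1 by 1.42 ± 0.29, and 0 rose (camera adjusted p = 0.513). Of 11 genes of antigen presentation 2 fell and 0 rose (camera adjusted p = 0.117), with Cd209a at least 1.55-fold lower. Of 7 T and NK cell genes 2 fell, such as the granzyme gene Gzma by 0.95 ± 0.18 (camera adjusted p = 0.117), of 5 B-cell genes 1 rose and 2 fell, with Cd79b up by 1.18 ± 0.32 (camera adjusted p = 0.613), and of 9 plasma cell genes 2 rose and 1 fell, with Mzb1 up by 1.45 ± 0.12 and Ighm down by 2.07 ± 0.56 (camera adjusted p = 0.627). Of 4 mast cell genes 1, Kit, rose by 1.05 ± 0.31 and 1, Cpa3, fell, mostly in values under the floor, being under 4 on 3 of 3 E7 and 2 of 3 wild-type arrays, with a difference of -0.06 when these are set to 4. Of 3 erythroid genes 1, Alas2, fell by 1.44 ± 0.24. Of 17 lysosomal genes 2 rose, such as Npc1 by 1.09 ± 0.28, and 4 fell, such as Neu1 by 1.02 ± 0.15 (camera adjusted p = 0.399). Of 20 genes of the unfolded protein response 6 fell and 0 rose (median -0.46, camera adjusted p = 0.00723, adjusted p = 0.877 with an estimated correlation), among them Herpud1 by 1.23 ± 0.28 and Sel1l by 0.58 ± 0.10, which act in degradation of proteins from the endoplasmic reticulum. Plasma cell genes had a median of 0.08 and a mean of -0.04, and chemokines a median of -0.21 and a mean of -0.10 with the test pointing up. Adjusted over the list alone, 0 interferon genes, 1 T and NK cell gene, 2 genes of the unfolded protein response and 2 erythroid genes fell, 1 chemokine rose and 1 fell, and 1 lysosomal gene rose and 3 fell. The other counts of these lists were the same.

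The E7 count rested most on the 6-month arrays: it was 2990 without the wild-type pool and 2998 without the E7 pool of that age, and without either of them the unfolded protein response was no longer called, with medians of -0.21 and -0.26. Of 91 named E7 calls, 80 held whichever array was left out, and the exceptions were Ccl2, Cd79b, Cpa3, Fos, Herpud1, Ighm, Kit, Mb, Neb, Npc1 and Pth.

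**Figure D1:**
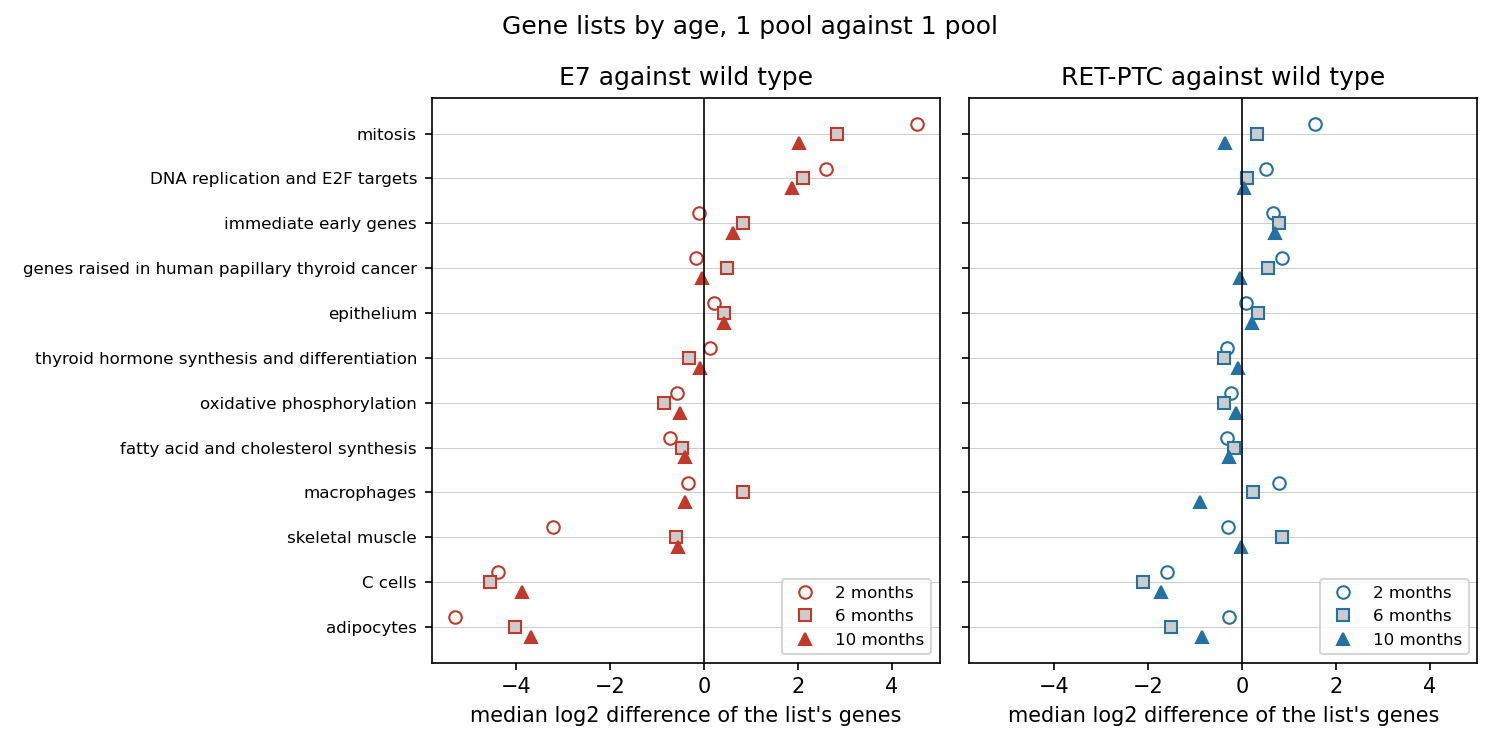
Median log2 difference from wild type (x axis) of the genes of 12 lists (y axis) in E7 and RET-PTC pools, 1 symbol per age, each 1 pool against 1 pool without a test. In E7 the mitosis medians are 4.52, 2.83 and 2.02 and the C-cell medians -4.37, -4.55 and -3.88 at 2, 6 and 10 months, while in RET-PTC pools the mitosis medians are 1.56, 0.33 and -0.36.

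RET-PTC against wild type asks what the kinase fusion changes. Sftpb, Sftpd, Sftpa1, Ereg, Csn2 and Csn3 were higher in RET-PTC pools and under 4 on all wild-type arrays, and the list of immediate early genes was called higher (adjusted p = 0.618 with an estimated correlation). The C-cell list was called lower (adjusted p = 0.383 with an estimated correlation). Of 11370 genes 1503 passed, 807 higher and 696 lower, with 292 higher and 238 lower by at least 2-fold. Sftpb, Sftpd and Sftpa1, which encode surfactant proteins of the lung, were at least 84.5-fold, 71.8-fold and 47.8-fold higher (Sftpb 10.40 ± 0.38 against 2.58 ± 0.00, SD, n = 3, limma adjusted p = 2.81e-06). Ereg, which encodes the receptor ligand epiregulin, was at least 79.3-fold higher and Sprr1a, of the cornified envelope, at least 44.0-fold. The casein genes Csn2 and Csn3 were at least 38.8-fold and 14.7-fold higher. In RET-PTC pools of 2, 6 and 10 months Csn2 was at 5.42, 11.31 and 11.10, and Csn3 at 7.86, 8.06 and 7.70. The claudin gene Cldn2 was at 8.64 ± 0.24 against 3.06 ± 0.22 (SD), with wild type at the floor, and Fxyd3, a sodium pump regulator gene, at least 25.7-fold higher, and St8sia6, a sialyltransferase gene, rose by 5.18 ± 0.18 (SE). Greb1, an oestrogen-responsive gene, fell at least 9.23-fold, and Olfm4 by 4.21 ± 0.26 (SE) on the log2 scale. Cxcl11, an interferon-induced chemokine gene, fell by 3.63 ± 0.49, Ak7, an adenylate kinase of cilia, by 3.54 ± 0.87, the aquaporin gene Aqp6 by 3.22 ± 0.36, Lmod2 by 3.20 ± 0.29 and Tesc by 3.05 ± 0.15. Ttr, which encodes the thyroid hormone carrier transthyretin, was at least 4.23-fold, Cckar at least 4.35-fold and Snx31 at least 2.89-fold lower. In RET-PTC pools Olfm4 was under 4 on 2 of 3 arrays and Ak7 and Aqp6 on 1, and with these set to 4 the differences were -3.71, -3.09 and -3.00.

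Thyroid and cancer-related lists were called in RET-PTC pools with few members past the threshold. Of 19 thyroid genes 2 rose and 2 fell (median -0.38, camera adjusted p = 0.0382, adjusted p = 0.407 with an estimated correlation). Dio1, the type 1 deiodinase gene, fell by 2.53 ± 0.27 (SE), from 12.72 ± 0.30 to 10.19 ± 0.43, and Slc5a8, an apical transporter gene, by 2.64 ± 0.44. Pax8 rose by 0.57 ± 0.11, and Sorbs2 rose from 10.32 ± 0.10 to 11.33 ± 0.04 (SD). With values under 4 set to 4, the thyroid median was -0.35. Of 26 genes raised in human papillary thyroid cancer 8 rose and 1 fell (median 0.50, 1.41-fold; camera adjusted p = 0.00422, adjusted p = 0.805 with an estimated correlation). Timp1, a protease inhibitor gene, rose by 4.02 ± 0.76 (SE), Muc1 by 3.87 ± 0.29, the transcription factor gene Runx1 by 3.14 ± 0.55, Hmga2 by 1.76 ± 0.24, the integrin gene Itga3 by 1.51 ± 0.18 and the keratin gene Krt19 by 0.70 ± 0.13. In wild type Muc1 and Runx1 were under 4 on 2 of 3 arrays and Timp1 on 1, and with these set to 4 the differences were 3.55, 2.71 and 3.88. The median of this list was 0.85, 0.56 and -0.03 at 2, 6 and 10 months, beside fibroblast medians of 0.72, 0.37 and -0.35 and macrophage medians of 0.79, 0.23 and -0.88, and Timp1 is also in the fibroblast list. Of 19 genes lowered in that cancer 2 rose and 6 fell (median -0.39, camera adjusted p = 0.0189, adjusted p = 0.407 with an estimated correlation), among them Tfcp2l1 by 1.02 ± 0.13 and Kit by 1.27 ± 0.31, and Lrp2, the thyroglobulin receptor megalin, rose by 0.67 ± 0.16. Of 18 epithelial genes 6 rose and 1 fell (median 0.25, camera adjusted p = 0.0196, adjusted p = 0.619 with an estimated correlation), with Epcam up by 0.61 ± 0.09, St14 by 0.55 ± 0.09 and Grhl2 by 0.42 ± 0.09. The other Epcam probe set changed by -0.20, short of the threshold. Adjusted over the list alone, 2 thyroid genes rose and 6 fell, 2 genes of the lowered list rose and 8 fell, and the other counts were the same.

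Immediate early genes rose in RET-PTC pools in 9 of 19 cases with 0 falling (median 0.61, 1.53-fold; camera adjusted p = 0.00107, adjusted p = 0.618 with an estimated correlation). Egr3, Egr2 and Egr1, transcription factor genes induced by growth signals, rose by 4.54 ± 0.23, 2.71 ± 0.23 and 2.60 ± 0.20 (SE), and Nr4a2 by 1.11 ± 0.13. The median of the list was 0.66, 0.79 and 0.70 at the 3 ages, and over all ages it was 0.94 without the 10-month RET-PTC pool. Of 16 genes of MAPK pathway output 4 rose and 1 fell, and the list was not called (median 0.15, camera adjusted p = 0.238). Fosl1 was at least 1.98-fold higher, Spred1 rose by 1.20 ± 0.11 and Dusp6 by 0.82 ± 0.15, while Spry1, another inhibitor of the pathway, fell by 0.84 ± 0.13. Among 17 p53 targets 2 rose and 0 fell (camera adjusted p = 0.259), the receptor gene Eda2r at least 2.62-fold and Cdkn1a by 1.01 ± 0.15. Of 38 genes of DNA replication and E2F targets 3 rose and 0 fell (median 0.28, camera adjusted p = 0.0366, adjusted p = 0.880 with an estimated correlation), namely Hells by 1.23 ± 0.29 (SE), Cdt1 by 0.98 ± 0.20 and Mcm3 by 0.69 ± 0.15. The 2 other Hells probe sets changed by -0.07 and 0.21. Of 31 mitosis genes 1, Cdk1, rose by 1.39 ± 0.23 (median 0.51, camera adjusted p = 0.0366, adjusted p = 0.880 with an estimated correlation). The mitosis median was 1.56 at 2 months, 0.33 at 6 months and -0.36 at 10 months. With values under 4 set to 4 the mitosis median over all ages was 0.47. Without the 2-month wild-type pool the mitosis median was -0.13 and without the 2-month RET-PTC pool 0.24, and the list was not called in either case, while without the 10-month wild-type pool the median was 0.97. As adjusted over the list alone, 9 immediate early genes rose and 2 fell, 5 MAPK genes rose and 1 fell, 0 genes of DNA replication rose, and the other counts were the same.

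C-cell and metabolic lists were lower in RET-PTC pools. Of 11 C-cell genes 8 fell and 0 rose (median -1.89, 3.69-fold lower; camera adjusted p = 1.43e-06, adjusted p = 0.383 with an estimated correlation). Snap25 fell by 2.63 ± 0.21 (SE), the prohormone convertase gene Pcsk1 by 2.45 ± 0.25, Resp18 by 2.37 ± 0.33 and Chgb by 2.27 ± 0.23. Snap25 was under 4 on 1 of 3 RET-PTC arrays, and its difference was -2.59 with that value set to 4. Of 13 adipocyte genes 3 fell and 0 rose (median -0.90, camera adjusted p = 0.000134, adjusted p = 0.618 with an estimated correlation), namely Retn by 1.07 ± 0.19 (SE), Cidec by 1.02 ± 0.24 and Cox7a1 from 9.61 ± 0.18 to 8.60 ± 0.52 (SD). Of 18 genes of fatty acid and cholesterol synthesis 3 fell and 0 rose (median -0.23, camera adjusted p = 0.00107, adjusted p = 0.407 with an estimated correlation), Acss2 by 1.25 ± 0.22, Fasn by 0.96 ± 0.18 and the carboxylase gene Acaca by 0.84 ± 0.10, beside that lower adipocyte median, and the median was -0.18 with values under 4 set to 4. Of 25 genes of oxidative phosphorylation 1, the cytochrome c gene Cycs, fell by 0.58 ± 0.14, and 0 rose (median -0.25, camera adjusted p = 2.62e-05, adjusted p = 0.618 with an estimated correlation), again beside an adipocyte median of -0.90. Of 17 genes of hypoxia and glycolysis 1 rose and 4 fell (median -0.14, camera adjusted p = 0.0189, adjusted p = 0.407 with an estimated correlation), with Egln3 at least 3.54-fold lower, Adm and Bnip3 down by 1.48 ± 0.16 and 1.12 ± 0.14 and Ndrg1 up by 1.62 ± 0.15. Of 20 genes of the unfolded protein response 4 fell and 0 rose (median -0.48, camera adjusted p = 1.99e-05, adjusted p = 0.618 with an estimated correlation), namely Herpud1 by 1.26 ± 0.28, Manf by 0.94 ± 0.23, Dnajb9 by 0.71 ± 0.15 and Sel1l by 0.55 ± 0.10. Without the 6-month wild-type pool the medians of the unfolded protein response and of oxidative phosphorylation were -0.295 and -0.166, and the hypoxia median was -0.27 and -0.08 without the RET-PTC pool of 2 and 10 months. With p adjusted over the list alone, 9 C-cell genes, 8 adipocyte genes, 5 genes of lipid synthesis, 0 of oxidative phosphorylation and 9 of the unfolded protein response fell, and the hypoxia counts were the same.

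Of the remaining lists, that of squamous epithelium was called higher in RET-PTC pools. Of 5 squamous genes 2 rose and 0 fell, Sprr1a and Pkp1, of which Pkp1 by 2.63 ± 0.21 (SE) (median 0.64, camera adjusted p = 0.00297, adjusted p = 0.397 with an estimated correlation), and Sprr1a is also expressed by other stressed epithelia. The mast cell protease genes Cpa3 and Tpsab1 rose by 2.88 ± 0.30 and at least 2.58-fold, and in all, 2 of 4 mast cell genes rose and 1, Kit, fell. Cpa3 was under 4 on 2 of 3 wild-type arrays, and its difference was 2.60 with these set to 4. Of 26 genes of fibroblasts and extracellular matrix 2, Timp1 and Tnc (0.77 ± 0.18), rose and 2, Tagln and Acta2, fell by 0.79 ± 0.13 and 0.73 ± 0.13 (camera adjusted p = 0.520). Of 15 chemokines and cytokines 2 fell, Cxcl10 by 2.73 ± 0.68 and Cxcl12 by 1.10 ± 0.12, and 0 rose (camera adjusted p = 0.520). Of 26 interferon response genes 1, Iigp1, rose by 0.96 ± 0.24, and 0 fell (camera adjusted p = 0.238). Of 9 plasma cell genes Sdc1, which epithelia also express, rose by 2.43 ± 0.27 and Derl3 fell by 1.89 ± 0.39 (camera adjusted p = 0.638). Of 6 cartilage genes Col9a1 rose by 2.56 ± 0.37 (camera adjusted p = 0.0761), of 20 muscle genes Myh8 was at least 1.86-fold lower (camera adjusted p = 0.914), of 17 lysosomal genes Lrp2 rose (camera adjusted p = 0.356), of 3 erythroid genes Alas2 fell by 1.04 ± 0.24 and of 2 thymocyte genes Cd1d1 fell by 0.97 ± 0.25. In the lists of macrophages (19 genes), antigen presentation (11), T and NK cells (7), B cells (5), endothelium (18), parathyroid (6), airway (6), neutrophils (3) and reference genes (8), 0 genes passed with limma. B-cell genes had a median of 0.05 and a mean of -0.11, chemokines a mean of -0.19 with a median above 0, and the T and NK cell and muscle lists medians of 0.04 and 0.17 with the test pointing down. Adjusted over the list alone, 3 squamous genes, 3 of fibroblasts, 0 of the interferon response and 0 lysosomal genes rose, 1 B-cell and 1 parathyroid gene fell, and the other counts were the same.

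The RET-PTC count changed by more than 1.5 times when any array of the compared genotypes was left out. It was 826, 545 and 800 without the wild-type pool of 2, 6 and 10 months, and 886, 510 and 701 without the RET-PTC pool of those ages, and with arrays centred on their medians the split was 672 higher and 873 lower. The number of lists called was 9 without the 6-month RET-PTC pool, against 14. Of 84 named RET-PTC calls, 26, 38 and 24 were lost without the wild-type pool of 2, 6 and 10 months, 22, 38 and 27 without the RET-PTC pool and 3, 15 and 15 without the E7 pool of those ages. In all, 42 held whichever array was left out, among them those of the surfactant genes, Ereg, Sprr1a, Csn3, Cldn2, Egr1, Egr2, Egr3, Dio1, Muc1, Snap25 and Chgb. Left out 1 at a time, 8 of the 9 arrays ended the calls of Cd1d1, Cycs, Grhl2, Lrp2 and Manf. The calls of Ak7, Cox7a1, Cxcl10, Dnajb9, Iigp1 and Mcm3 ended with 7 of them. Those of Acta2, Cdt1, Cidec, Hells, Herpud1, Kit and Tnc ended with 6. Leaving out an array ended the calls of the thyroid list (wild type at 2 or 6 months, RET-PTC at 6 months), of DNA replication and mitosis (wild type or RET-PTC at 2 months, RET-PTC at 6 months), of the epithelium list (either pool at 6 months), of hypoxia (wild type at 2 months, RET-PTC at 6 months) and of the list raised in papillary cancer (RET-PTC at 2 months). Besides those given above, medians that moved by more than 1.5 times were those of the thyroid list (-0.23) and the list raised in papillary cancer (0.25) without the 2-month RET-PTC pool, of DNA replication (0.07) without the 2-month wild-type pool and of epithelium (0.14) without the 6-month wild-type pool.

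**Figure D2:**
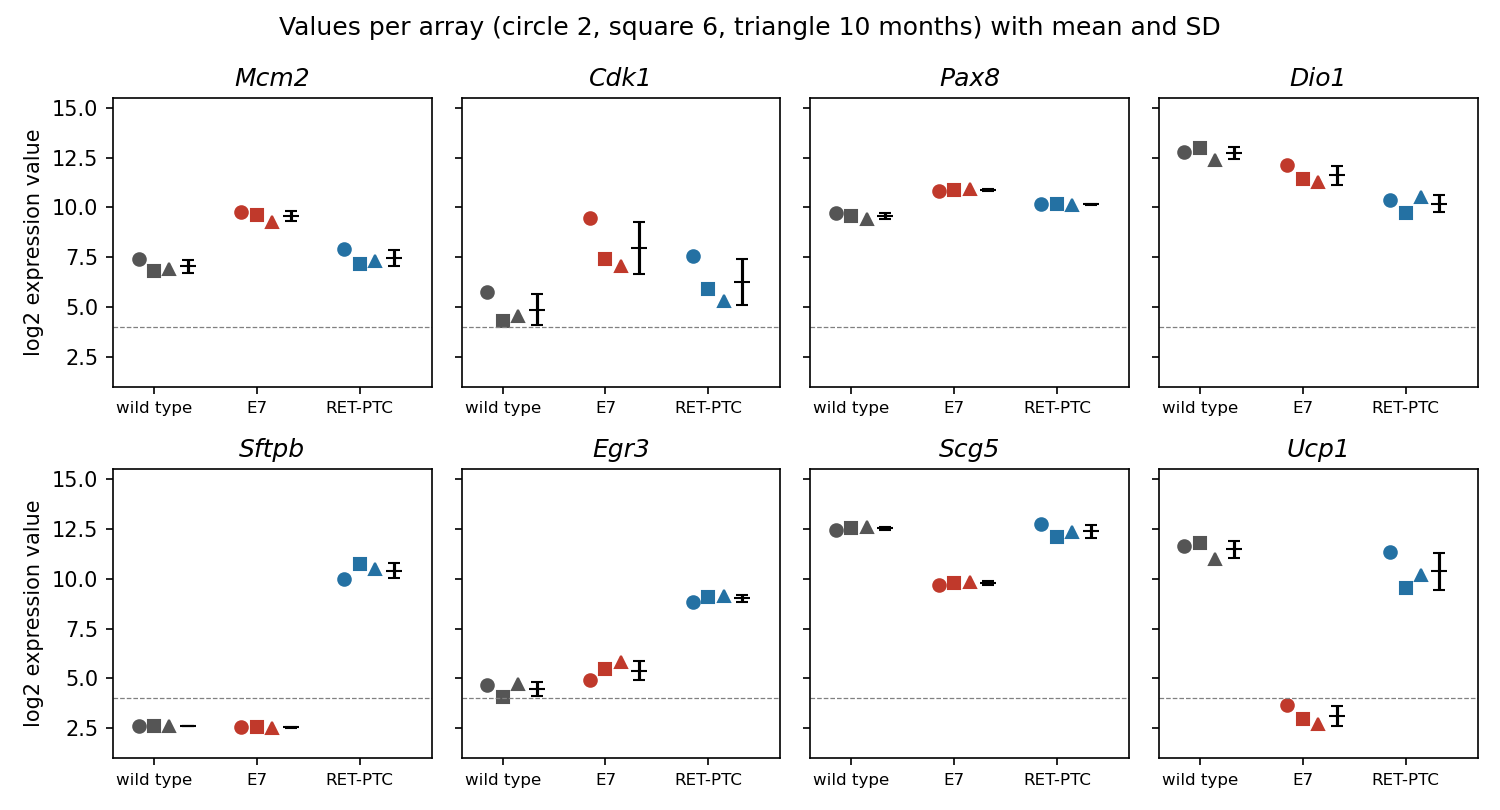
Values per array on the log2 scale (y axis) of 8 genes in the 3 genotypes (x axis), with circles at 2, squares at 6 and triangles at 10 months, a bar for the mean with its SD over the 3 ages, and a dashed line at 4, under which values are bounds. Sftpb is at 10.40 ± 0.38 in RET-PTC pools and at 2.58 ± 0.00 in wild type, and Ucp1 at 3.10 ± 0.48 in E7 pools against 11.48 ± 0.43 in wild type.

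RET-PTC against E7 compares the 2 transgenic strains directly. The adipocyte list was called higher in RET-PTC pools, and the mitosis and DNA replication lists were called higher in E7 pools (adjusted p = 0.762 with an estimated correlation for each). Of 11370 genes 4169 passed, 2272 higher in RET-PTC pools and 1897 lower, with 752 higher and 602 lower by at least 2-fold. Sftpb was at least 84.5-fold, Ucp1 at least 82.6-fold, Ereg at least 79.3-fold, Sftpd at least 71.8-fold and Sftpa1 at least 47.8-fold higher in RET-PTC pools. Mmp12, the macrophage elastase gene, was at least 73.9-fold lower in them, Lockd at least 17.9-fold, Krtap17-1 at least 11.5-fold and Greb1 at least 7.38-fold, and Wfikkn2 was lower by 5.63 ± 0.13 (SE) on the log2 scale. Of 31 mitosis genes 31 were lower in RET-PTC pools (camera adjusted p = 2.64e-13, adjusted p = 0.762 with an estimated correlation), among them Pbk by 2.87 ± 0.25. Of 38 genes of DNA replication and E2F targets 35 were lower and 0 higher (camera adjusted p = 1.35e-19, adjusted p = 0.762 with an estimated correlation), with Mcm2 lower by 2.10 ± 0.13. Of 13 adipocyte genes 11 were higher and 0 lower (camera adjusted p = 1.53e-07, adjusted p = 0.762 with an estimated correlation), Retn at least 43.8-fold and Cidec at least 16.8-fold. Of 11 C-cell genes 9 were higher and 1 lower (camera adjusted p = 0.000237, adjusted p = 0.762 with an estimated correlation), with Resp18 at 8.01 ± 0.68 against 3.46 ± 1.29 and Chgb higher by 3.17 ± 0.23. Both were under 4 on 2 of 3 E7 arrays and Wfikkn2 on 1 of 3 RET-PTC arrays, and with these set to 4 the differences were 3.70 for Resp18, 2.64 for Chgb and -5.52 for Wfikkn2. Of 26 genes of fibroblasts and extracellular matrix 10 were higher and 0 lower (camera adjusted p = 0.00162, adjusted p = 0.762 with an estimated correlation), among them Pdgfra by 1.74 ± 0.28 and Thy1, at 8.02 ± 0.19 against 6.51 ± 0.27 (SD). Of 20 muscle genes 7 were higher and 0 lower (camera adjusted p = 0.00162, adjusted p = 0.762 with an estimated correlation). Of 25 genes of oxidative phosphorylation 18 were higher and 0 lower (camera adjusted p = 1.85e-05, adjusted p = 0.762 with an estimated correlation), beside an adipocyte median higher by 3.75. Egr3 and Egr1 were higher in RET-PTC pools by 3.63 ± 0.23 and 2.01 ± 0.20, and the interferon-induced gene Ifit1 by 1.92 ± 0.29, while the lists of immediate early and interferon response genes were not called (camera adjusted p = 0.0974 and 0.0759). Adjusted over the list alone, 12 adipocyte, 10 C-cell, 11 fibroblast and 20 oxidative phosphorylation genes were higher, and the other counts of called lists were the same. The count was 2740 without the 6-month E7 pool and 2585 and 2679 without the RET-PTC pools of 6 and 10 months, and all 21 named calls held whichever array was left out. Without the 2-month E7 pool the medians of fibroblasts and muscle were 0.33 and 0.86, against 0.67 and 1.65, and that of fibroblasts was 0.34 without the 2-month RET-PTC pool. Called lists numbered 13 without the 6-month E7 pool and 17 without the 10-month RET-PTC pool, against 7.

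Changes of both transgenic strains from wild type were set against each other across genes, which are not independent replicates. The correlation of the 2 sets of log2 changes was 0.322, against 0.503 simulated for 2 unchanged groups with the same 3 wild-type arrays. The same sign was seen in 65.5% of genes, against 66.7% simulated. The simulated changes are noise alone, and their correlation comes from the shared wild-type arrays. The observed changes also hold differences of each strain, so the lower observed correlation does not show less agreement. The covariance was 0.162, against 0.0186 simulated, a difference of 0.143. Of the genes that passed, 346 were higher in both strains and 395 lower in both, where independent lists would share 161.8 and 143.9. There were 65 higher in E7 and lower in RET-PTC pools, and 100 the other way, where independent lists would share 139.5 and 166.9. Both sets of calls use the same 3 wild-type arrays, which are too few to split, so what those arrays share is part of the overlap.

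The comparison of 10 with 2 months asks what changed with age over all 3 genotypes. Of 11370 genes 34 passed, 16 higher and 18 lower. Dbp, a clock-controlled transcription factor gene, rose by 4.20 ± 0.44 (SE), from 9.25 ± 0.72 to 13.44 ± 0.60 (SD over 3 genotypes, limma adjusted p = 0.0482), Per2, a clock repressor gene, by 2.77 ± 0.32 and Tef, a relative of Dbp, by 2.74 ± 0.17 (limma adjusted p = 0.00614). Npas2, a clock activator gene, fell by 1.65 ± 0.16. Mamdc2 rose by 3.25 ± 0.11 (limma adjusted p = 0.000338) and the transcription factor gene Zbtb16 by 2.49 ± 0.31, while Pbk fell by 2.28 ± 0.25, Cdk1 by 1.95 ± 0.23, Bcas1 by 1.80 ± 0.21 and Endou by 1.69 ± 0.17. All 10 had the same sign in all 3 genotypes, which the rule for naming required. Mamdc2 was under 4 on 1 of 3 arrays at 2 months and Npas2 on 1 of 3 at 10 months, and with these set to 4 the differences were 3.13 and -1.62. The count was small and unstable: it was 7 and 2 without the wild-type pool of 6 and 10 months, 3, 8 and 1 without the E7 pool of 2, 6 and 10 months, and 4 and 3 without the RET-PTC pool of 6 and 10 months. Of 17 settings of the analysis Dbp passed in 4, Per2 in 3 and Tef in 13. Of the 10 named genes only Mamdc2 held whichever array was left out, and between 4 and 9 of them were lost when 1 array was left out.

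**Figure D3:**
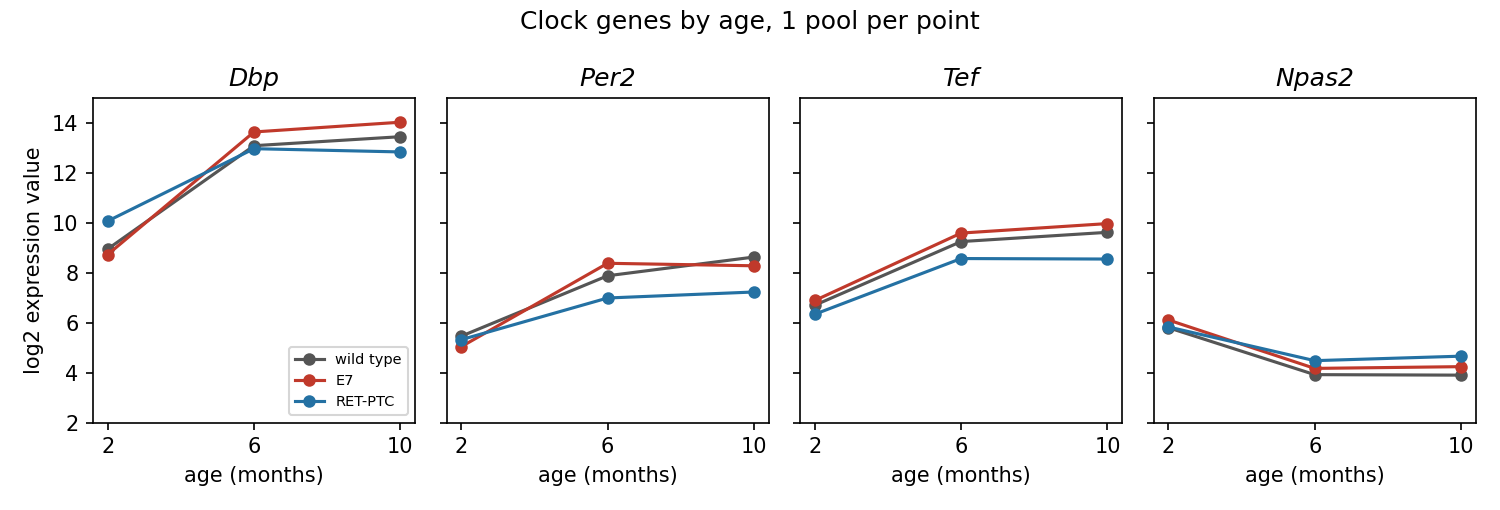
Log2 expression values (y axis) of the clock genes Dbp, Per2, Tef and Npas2 by age in months (x axis), 1 line per genotype and 1 pool per point. In wild type Dbp is at 8.95, 13.09 and 13.45, and Npas2 is lower at 10 than at 2 months in all 3 genotypes, as the naming rule required.

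Gene lists also differed between 10 and 2 months. Of 31 mitosis genes 2 fell and 0 rose, 29 adjusted over the list alone (median -1.62, camera adjusted p = 8.77e-17, adjusted p = 0.864 with an estimated correlation). The medians within wild type, E7 and RET-PTC were -0.16, -2.50 and -2.04. Genes of DNA replication (median -0.40), C cells (-1.01), the interferon response (-0.31) and the unfolded protein response (-0.29) were called lower (camera adjusted p = 7.24e-09, 8.99e-06, 0.000243 and 0.00884, adjusted p = 0.864, 0.567, 0.864 and 0.864 with an estimated correlation). Skeletal muscle (median 1.16), macrophages (0.70), antigen presentation (0.55), immediate early genes (0.31), lysosome (0.21) and epithelium (0.14) were called higher (camera adjusted p = 5.21e-06, 0.000243, 0.0168, 0.0168, 0.0142 and 0.0118, adjusted p = 0.864 for each with an estimated correlation). In RET-PTC pools 4 of these lists had medians of the other sign: within wild type, E7 and RET-PTC they were 1.28, 1.21 and -0.35 for macrophages, 0.69, 1.30 and -0.37 for antigen presentation, 0.15, 0.63 and -0.02 for immediate early genes, and 0.28, 0.46 and -0.16 for the lysosome. In these 10 lists 0 genes passed over all genes tested, and adjusted over the list alone 9 C-cell, 1 DNA replication and 1 interferon gene fell and 2 epithelial genes rose. Within wild type, E7 and RET-PTC the muscle medians were 0.20, 3.28 and 0.52 and those of DNA replication 0.05, -0.87 and -0.35. The calls of mitosis, DNA replication, C cells and muscle held whichever array was left out, but the muscle median was 0.53 and 0.56 without the E7 pool of 2 and 10 months and 1.89 without the 2-month wild-type pool, and that of DNA replication -0.18 without the 2-month E7 pool. In all, 7 lists were called without the 2-month E7 pool, against 11. Those of macrophages, antigen presentation, the lysosome, immediate early genes and the unfolded protein response ended without the 10-month wild-type or the 2-month E7 pool, those of antigen presentation and the lysosome also without the 2-month wild-type pool and that of immediate early genes also without the 10-month E7 pool, that of epithelium without the 2-month E7 or RET-PTC pool and that of the interferon response without the 2-month or 10-month RET-PTC pool. Without the 2-month E7 pool the medians were 0.29 for macrophages, 0.14 for antigen presentation, 0.17 for immediate early genes, 0.04 for the lysosome, 0.08 for epithelium and -0.53 for the interferon response. Without the 10-month wild-type pool they were 0.31 for macrophages, 0.26 for antigen presentation, 0.11 for the lysosome and -0.52 for the interferon response, and without the 2-month wild-type pool 0.25 for epithelium. Without the RET-PTC pool of 2 and 10 months they were 1.19 and 1.06 for macrophages, 0.89 and 0.87 for antigen presentation, 0.34 and 0.32 for the lysosome and -0.19 and -0.12 for the interferon response.

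Age slopes ask whether a transgene's effect grew or shrank between 2 and 10 months. For RET-PTC against wild type 0 of 11370 genes passed with limma (598 at an unadjusted p under 0.05, smallest adjusted p = 0.169). The differences in slope with the smallest p were those of Cuzd1, Rims2, Esrrg, Nme4 and Pcyt1b upwards, at 0.33, 0.20, 0.29, 0.17 and 0.17 per month on the log2 scale, and of Bpifa1, Cyp2f2, Cldn1, Wee1 and Birc5 downwards, at -0.49, -0.29, -0.42, -0.19 and -0.39, and none of them passed. Cuzd1 was at 5.58, 6.67 and 8.17 in RET-PTC pools of 2, 6 and 10 months and under 4 on all wild-type arrays, so its slope difference rests on wild-type values that are only bounds. The airway gene Bpifa1 differed from wild type by 3.57, 1.45 and -0.37 at these ages, in single pools without a test. Without the 10-month RET-PTC pool 2 genes passed. At the level of lists 16 were called, 1 higher and 15 lower in slope. Mitosis genes had a median slope difference of -0.25 per month (camera adjusted p = 9.14e-23, adjusted p = 0.475 with an estimated correlation) and macrophage genes one of -0.21 (camera adjusted p = 2.36e-11, adjusted p = 0.478 with an estimated correlation). The mitosis difference was -0.092 without the 2-month and -0.413 without the 10-month RET-PTC pool. From 2 to 10 months the macrophage median moved by 1.28 in wild type, 1.21 in E7 and -0.35 in RET-PTC pools, and without the 10-month wild-type pool the macrophage list was not called, with a slope difference of -0.011. The macrophage difference was -0.09 without the 2-month RET-PTC pool, with the list still called, and -0.313 and -0.398 without the 10-month RET-PTC and the 2-month wild-type pool.

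For E7 against wild type 0 genes passed for slope with limma (848 at an unadjusted p under 0.05, smallest adjusted p = 0.253). The smallest p belonged to Chga, Npr3, Tnmd, St6galnac6 and Pcyt1b upwards, at 0.45, 0.32, 0.45, 0.28 and 0.23 per month, and to 6720489N17Rik, E2f8, Kank4, Trabd2b and Cenpn downwards, at -0.29, -0.27, -0.25, -0.23 and -0.32, and none of them passed. The C-cell gene Chga was below wild type by -5.27, -3.34 and -1.70 at 2, 6 and 10 months. E2f8, an E2F repressor gene, was at 6.31, 5.27 and 4.33 in E7 pools of these ages. E2f8 and Cenpn were under 4 on all wild-type arrays and Pcyt1b on all E7 arrays, so their slope differences rest on values that are only bounds. Of the lists, 3 were called higher and 3 lower in slope. Mitosis and DNA replication genes had median slope differences of -0.30 and -0.12 per month (camera adjusted p = 3.26e-25 and 2.08e-18, adjusted p = 0.674 for each with an estimated correlation), and skeletal muscle and parathyroid genes of 0.39 and 0.25 (camera adjusted p = 0.00289 and 4.05e-05, adjusted p = 0.995 and 0.555 with an estimated correlation). Without the 2-month E7 pool the mitosis and DNA replication differences were -0.11 and -0.028, and without the 10-month E7 pool -0.483 and -0.198. The muscle list was not called without the 10-month wild-type pool, at 0.21, and was called lower without the 2-month E7 pool, at -0.13. Called lists numbered 18 and 15 without the wild-type pool of 2 and 10 months and 11 without the E7 pool of either age, against 6.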

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

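The tests on single pools and on RNA quality here were chosen only after the results were seen, and the slope tests before. By a test of the difference itself, age slopes of 16 gene lists differed between RET-PTC and wild type and those of 6, partly the same lists, between E7 and wild type, by camera with the preset correlation, and 0 of them with an estimated correlation. For RET-PTC, median slope differences per month on the log2 scale were negative for airway epithelium (-0.391), mitosis (-0.249), macrophages (-0.208), cartilage (-0.191), T and NK cells (-0.147), chemokines and cytokines (-0.135), antigen presentation (-0.125), fibroblasts and extracellular matrix (-0.116), interferon response (-0.079) and adipocytes (-0.079). They were also negative for genes raised in human papillary thyroid cancer (-0.073), DNA replication (-0.067), MAPK pathway output (-0.051), lysosome (-0.051) and endothelium (-0.037), and positive for parathyroid (0.13). For E7 they were negative for mitosis (-0.296), airway epithelium (-0.185) and DNA replication (-0.116), and positive for skeletal muscle (0.387), parathyroid (0.246) and immediate early genes (0.096). Calls held whichever array was left out for airway epithelium, mitosis, cartilage and lysosome in RET-PTC and for mitosis, DNA replication and parathyroid in E7, but without 1 array 15 of the 16 medians in RET-PTC and 5 of the 6 in E7 turned or changed in size by more than 1.5 times. Without the 2-month RET-PTC pool those of RET-PTC mitosis and lysosome were -0.092 and -0.032, without the 10-month RET-PTC pool that of mitosis was -0.413, and RET-PTC cartilage was at -0.305 and -0.097 without the wild-type pool of 2 and 10 months. E7 mitosis and DNA replication were at -0.11 and -0.028 without the 2-month E7 pool and at -0.483 and -0.198 without the 10-month E7 pool. In RET-PTC the other calls ended without 1 array. This was the 2-month RET-PTC pool for DNA replication, MAPK output, T and NK cells, adipocytes, chemokines, endothelium, interferon response and parathyroid. It was the 10-month wild-type pool for macrophages, antigen presentation, fibroblasts, genes raised in papillary cancer, MAPK output, chemokines and parathyroid, the 2-month wild-type pool for T and NK cells, adipocytes and parathyroid, and the 10-month RET-PTC pool for endothelium. Without the 10-month wild-type pool the endothelium and interferon lists were instead called higher, at 0.086 and 0.12, and the medians of antigen presentation, fibroblasts and chemokines were 0.002, 0.013 and 0.014. In E7 the muscle list was not called without the 10-month wild-type pool, at 0.209, and was called lower without the 2-month E7 pool, at -0.125. The airway call in E7 ended without the 10-month wild-type pool, at -0.076, or the 10-month E7 pool, at -0.204, and that of immediate early genes without the 2-month wild-type pool, at 0.011, or the 2-month E7 pool, at 0.024.

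Most of these slopes were lower in RET-PTC pools than in wild type. Without the 10-month wild-type pool the macrophage difference was -0.011 per month and the list was no longer called, so that pool may carry this part, although the difference was also closer to 0, at -0.09, without the 2-month RET-PTC pool, and a true rise of macrophages in ageing wild-type glands stays open with 1 pool. Without the 2-month RET-PTC pool the mitosis difference was -0.092 and the list was still called, which does not settle how much of it that pool carries. Degraded RNA on the 2-month RET-PTC array is argued against by its actin 3' minus 5' difference of 1.766, inside the range of the other 8 arrays, 1.61 to 2.13. A lower rate of cell division with age in RET-PTC glands stays open and was not tested further.

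A control probe set, which none of the comparisons use, stood apart on 1 array. The 5' probe set for 18S ribosomal RNA was at 14.166 on the 2-month RET-PTC array and at 7.39 to 8.62 on the wild-type arrays. It was at 7.34 to 8.78 on the E7 arrays and at 7.47 and 6.97 on the RET-PTC arrays of 6 and 10 months. The middle and 3' probe sets of the same RNA were at 8.98 and 8.18 on the 2-month RET-PTC array.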

How the results depend on the processing

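Comparisons of ages 10 with 6 and 6 with 2 months were chosen only after the data were seen, and the other alternatives before. Of 226 results for named genes 0 reversed in any setting. Genes were named for passing with a steady sign or for a small p, so reversals were unlikely from the start. The named results kept their side of the threshold in 2453 runs with other settings and 1722 leaving out an array, and fell below it in 302 and 312. The named slope genes did not pass in the main analysis and so could not be lost. The causes of the moves below were not tested, except that settings with fewer arrays leave fewer residual degrees of freedom and that testing every probe set raises the number of tests. For 10 against 2 months the count of genes, 34 in the main analysis, was 3 without a filter, 68 with a filter at 6, 3 with arrays centred on their median, 3 after a further quantile normalization, 84 with trend and robust variances, 21 with the mean of all probe sets, 8 with every probe set on its own and 0 without a genotype term (388 at an unadjusted p under 0.05). The count was 0 for 10 against 6 months (367 unadjusted) and 9 for 6 against 2 months, where 6 lists were called. Every probe set on its own gave 9604 for E7, 2541 for RET-PTC and 8301 for RET-PTC against E7. Without the 2-month arrays RET-PTC had 974, and without the E7 arrays 968. Without the 6-month arrays E7 had 1520, RET-PTC 169 and RET-PTC against E7 1443, and without the 10-month arrays 2479, 250 and 1934. Lists for RET-PTC against E7 numbered 14 and 17 without the 6-month and 10-month arrays. With an estimated correlation 0 lists were called in each of the 6 comparisons, and 1, 3, 1, 1, 2 and 1 had an unadjusted p under 0.05. Leaving out 1 array at a time gave 2990 to 4566 genes for E7, 510 to 1667 for RET-PTC, 2585 to 3924 for RET-PTC against E7, 1 to 31 for age, and 0 to 2 for the RET-PTC slope. Lists ranged from 9 to 20 for RET-PTC, 7 to 17 for RET-PTC against E7, 7 to 13 for age and 6 to 18 for the E7 slope, and the correlation of both strains' changes from 0.292 to 0.386. A further scaling moved the median change of all genes to at most 0.063. No paired analysis was made, since the replicate numbers are names in accession order, and the ages they follow are already a term of the model. Dim signal limits genes under 4, for which folds are bounds.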

Other observations

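The tests here on dilution, scaling, gradual change, the daily cycle and the other splits were chosen only after their results were seen, and those on further fat markers and glucocorticoid-induced genes before. Single pools differed in inflammatory genes. In E7 the neutrophil list (3 genes) had a median of 4.94 above wild type at 6 months, at the 100th percentile of 10000 random lists, and of 0.05 and 0.16 at 2 and 10 months. S100a8, a calprotectin gene chosen after its values were seen, was at 6.51, 10.18 and 8.62 in E7 pools and at 5.94, 5.24 and 8.47 in wild-type pools of 2, 6 and 10 months, so both genotypes varied with age. From 2 to 10 months the macrophage median moved by -0.35 in RET-PTC pools, 1.28 in wild type and 1.21 in E7. The airway median moved by -1.44, 1.69 and 0.46 in the same order.

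Fat and C-cell markers were lower in E7 pools. Dilution of all other cell types alike by more follicular tissue is argued against by unequal medians. Those of endothelium, macrophages and fibroblasts were 0.223, 0.119 and -0.305, and those of fat and C cells -4.17 and -4.03. The airway, muscle and parathyroid medians were below wild type too, at -1.637, -1.511 and -1.449. An unequal dilution, of only some cell types, was not tested and stays open. For scaling of the E7 arrays, 18 spiked-in hybridization controls had a median difference of -0.129 from wild type in the normalized values. These values had already been quantile-normalized, which made a large difference unlikely from the start. The controls therefore do not decide on scaling. Scaling before that step was not tested. Less fat tissue in the E7 pools is a candidate explanation for the fat part. Of 19 further fat markers, 0 of them in another list, 17 fell and 1 rose in E7 pools, with a median of -2.405. With the adipocyte list already lower, a fall of these markers was likely from the start, so it does not decide the cause. In RET-PTC pools 9 of them fell and 0 rose, with a median of -0.806. How many of the 19 thyroid cells also express was not tested. The abundant fat gene Fabp4 was still at 12.87 in E7 pools, fat at dissection and fat in the gland were not told apart, and an effect of E7 on C cells stays open and untested.

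Clock genes differed between 2 months and the later ages. For 8 genes that peak with Dbp, a gradual change with age as the only cause is argued against. Their median step from 2 to 6 months was 2.51, 2.82 and 1.95 in wild type, E7 and RET-PTC. From 6 to 10 months it was 0.11, -0.01 and -0.06, a share of 0.006 over the 3 genotypes. Other genes were not covered by this, nor was a gradual change offset by another harvest time at 6 or 10 months. The 2-month glands may have been taken at another point of the daily cycle: these genes rose and 3 genes of the opposite phase fell by median from 2 to 6 months in 3 of 3 genotypes, by 2.51 and -1.89 in wild type. These genes were picked because of the pattern, so the test of the daily cycle settles nothing, and age and harvest cannot be told apart here. Glucocorticoid-induced genes, which also follow a daily cycle, rose by more than 0.2 in 1 of 3 genotypes (medians 0.07, 0.26 and 0.01 in wild type, E7 and RET-PTC), which does not decide it.

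Other splits of the 6 arrays compared were too few, at 10, for a share under 0.05. For genes, E7 against wild type had 4630 calls and the highest other split 0, RET-PTC against wild type 1503 and 1, RET-PTC against E7 4169 and 0, 10 against 2 months 34 and 0, and in each of these 1 split, the real one, gave as many. For both slopes all 10 splits gave 0 genes. Every split other than the real one mixes arrays of both groups, so any difference between them stays partly and also adds to the error. The gene counts of those splits therefore do not show what unchanged groups would give. For lists the splits with at least as many calls numbered 7 for E7 (9 calls, highest other 18), 6 for RET-PTC (14, highest other 19), 9 for RET-PTC against E7 (7, highest other 19), 7 for age (11, highest other 16), 4 for the RET-PTC slope (16, highest other 21) and 7 for the E7 slope (6, highest other 14). In each comparison another split called more lists than the real one, with the preset correlation. With an estimated correlation 0 lists were called in the real comparisons, and what makes the other splits call lists was not tested.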
